A study of Mus musculus with 18 samples.

How the data were processed

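RNA of 18 libraries was analysed, from microglia and astrocytes that were enzymatically isolated with inhibitors and sorted by flow cytometry from the brains of tamoxifen-treated mice. Per the labels, libraries were sequenced as paired reads of 61 bp. The authors deposited TPM values, already scaled within each library, as 1 file per library with 1 decimal, so values under 0.05 TPM are listed as 0. The submitters' processing notes name Trim Galore 0.4.2, cutadapt 1.9.1, STAR 2.6.1e and featureCounts 1.6.2 and the genome build mm10, without their roles, the gene annotation, the strand setting or the treatment of reads that map to several places. Values of overlapping or antisense genes and of close paralogs, such as H2-Q6 and H2-Q7, are therefore uncertain. Each library's TPM values sum to the same total within rounding, so the files keep no read depth, and no counting interval or detection floor is given. All files listed the same 35869 gene symbols, of which 32401 were found in a RefSeq gene table. Positions were taken from GENCODE M21 (GRCm38).

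Groups followed cell type and genotype in the labels: control microglia (n = 4), KO microglia (n = 4), control astrocytes (n = 5) and KO astrocytes (n = 4). The remaining library has the title of a control astrocyte library that another library also has, while its sample code ends like those of microglia, and it was left out of all comparisons. Groups, comparisons, gene lists, the rule for named genes and most alternative settings were fixed before the data were examined.

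TPM values were log2-transformed after adding 1 TPM. Genes with at least 1 TPM in at least 4 libraries of a fit were tested with the moderated test of limma 3.58.1 in R 4.3.3, with a variance trend, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Genotypes were compared within each cell type with a spread estimated in that cell type. The difference of the KO effect between cell types was a contrast over all 17 libraries, and control microglia were compared with control astrocytes. Tgfb1 was also tested alone with an exact two-sided permutation test of log2(TPM + 1). Overlap of calls was tested with a one-sided Fisher's exact test for each direction over genes tested in both cell types.

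Gene lists, 32 with 638 genes of which 3 were not in the files, covered TGF-beta signalling, microglial and astrocyte states, immune and metabolic pathways, stress, and markers of the other brain and blood cell types. Each list with at least 3 tested genes was tested with limma's camera at a preset correlation of 0.01 between genes, which compares its genes with all other genes, and adjusted over the lists. An estimated correlation and the rotation test fry were alternatives. Counts of members are over all genes tested and, where stated, adjusted over the list alone. Several lists share genes and their members are co-expressed, so the list results are not independent of each other.

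The text names Tgfb1 and these genes: in each genotype comparison the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 TPM in the higher group and no overlap between groups, leaving out unnamed predicted genes. For each list up to 4 tested members with the smallest p among those past the threshold were named, or the 2 with the smallest p, as values, where none passed. A fixed set of microglial and astrocyte genes and the 5 largest differences between cell types in each direction were always named. Genes outside this rule are stated to have been chosen after their values were seen.

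Each pipeline was tested on simulated data with the same group sizes, in which 200 genes were changed by 1 or 2 on the log2 scale. In the microglial design 50% of the smaller and 87% of the larger changes were recovered, in the astrocyte design 49% and 87%, in the contrast of cell types 37% and 78%, and between cell types 47% and 91%. False calls made up between 3.52% and 5.56% of calls, and 0 had the wrong sign. The simulated noise was independent between genes and held no structure shared by libraries. The real astrocyte libraries held such a structure, so these rates need not hold for them. The changed genes were drawn from those with a mean log2(TPM + 1) above 1. In the real microglia 3711 genes were called, far more than 200, so the rates need not hold there either. Alternative settings fixed in advance were pseudocounts of 0.1 and 5 TPM, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, no variance trend, array weights, the replicate number as a block, 1 fit over all groups, and leaving out each library. After the data were seen, fits were added with Y-linked RNA as a covariate, with each kind of control alone, with the mural marker level as a covariate, and without KO astrocyte libraries 1 and 3, and quantile normalization was added for gene lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.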

Results

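RNA was sequenced from microglia and astrocytes sorted by flow cytometry from the brains of adult C57BL/6 mice given 5 oral doses of tamoxifen at 180 mg/kg. Control mice carried Cx3cr1CreERT2, a tamoxifen-inducible recombinase made by microglia and other Cx3cr1-expressing macrophages. Mice called KO here also carried loxP-flanked alleles of Tgfb1, the gene of transforming growth factor beta 1. The comparisons used 17 libraries: control microglia (n = 4, animals 1, 2, 4 and 5), KO microglia (n = 4), control astrocytes (n = 5) and KO astrocytes (n = 4). Another library was left in no group because its title and its sample code name different cell types. Each library held TPM values, a share of transcripts scaled to a fixed sum, for 35869 gene symbols with 1 decimal, and the read depth behind each value is unknown. Between 12456 and 12849 genes reached 1 TPM in control microglia of the comparisons and between 12903 and 13127 in KO microglia, without overlap. In astrocytes between 14086 and 15011 did in controls and between 14674 and 15484 in KO animals. Whether depth or expression lies behind the difference in microglia cannot be told from these values. Fold changes below are differences of log2(TPM + 1), which understate changes of genes near 1 TPM, and their p-values come from limma with Benjamini-Hochberg adjustment.

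Animals of the groups differed in sex-linked RNA. Xist, which is expressed from the inactive X chromosome, lay between 28.6 and 48.3 TPM in all 8 KO libraries and in those of control animals 1 and 2, where Ddx3y, a Y-linked gene, was at most 0.1 TPM. Control animals 3, 4 and 5 had no Xist RNA and between 46.0 and 56.3 TPM of Ddx3y in their libraries. Counts of calls between genotypes within a cell type are therefore also given against each kind of control. Control animals 1 and 2 also had more genes listed at 0. In microglia these were 18622 and 19175, against 17119 and 17963 in animals 4 and 5. In astrocytes they were 16790 and 17251, against 14902 to 15411 in animals 3, 4 and 5. Differences between the kinds of control can therefore not be assigned to sex.

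Control microglia were compared with control astrocytes to see how far each sort held its cell type. Homeostatic microglial genes were higher in control microglia for 31 of the 34 tested members and lower for 2 (limma camera, adjusted p = 5.5e-16; adjusted p = 0.00434 with an estimated correlation). All 22 astrocyte markers were lower in microglia (adjusted p = 2.0e-12; adjusted p = 0.0415 with an estimated correlation). P2ry12, a purinergic receptor of microglia, was at 3747 ± 273 TPM (SD, n = 4) in control microglia and 11.3 ± 2.53 TPM (SD, n = 5) in control astrocytes. Slc1a2, the main astrocytic glutamate transporter, was at 340.2 ± 24.1 TPM (SD, n = 5) in control astrocytes. The astrocyte libraries also held RNA of other brain cells. All 16 oligodendrocyte markers were lower in microglia than in astrocytes (camera adjusted p = 8.6e-07, and 0.218 with an estimated correlation). Their mean log2(TPM + 1) was 8.463 in control and 9.14 in KO astrocyte libraries, against 9.507 and 9.225 for astrocyte markers. Oligodendrocyte RNA was thus no minor part of these libraries. Of 13 tested mural and fibroblast-like markers, 12 were lower in microglia (adjusted p = 0.00480; adjusted p = 0.328 with an estimated correlation). Border-associated macrophage markers were higher in microglia for 14 of 16 and lower for 1 (adjusted p = 2.7e-06; adjusted p = 0.197 with an estimated correlation). limma called 10078 of 15332 genes, 4016 higher and 6062 lower in microglia. The median log2 difference of all genes was -0.19 and moved to 0.11 with quantile normalization, which called 5534 higher and 4850 lower, so the balance of directions depends on the scaling.

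Tgfb1, the targeted gene, was low in every library. It lies on chromosome 7 from 25687002 to 25705077 on the plus strand (GRCm38 coordinates, mm10 build). In microglia its level was 3.00 ± 0.271 TPM in controls (SD, n = 4) and 1.70 ± 0.294 TPM in KO animals (SD, n = 4). The control values of 2.8 to 3.4 TPM did not overlap the KO values of 1.3 to 2.0 TPM, and an exact two-sided permutation test gave p = 0.0286, the smallest that its 70 assignments allow. The log2 fold change was -0.57 with an SE of 0.16 (limma, adjusted p = 0.0258). It was -0.62 against controls without Y-linked RNA (adjusted p = 0.0718) and -0.52 against those with it (adjusted p = 0.0731). The limma call ended without control animal 1 (adjusted p = 0.0546) or 4 (0.0539) and without KO animal 1 (0.0625), 2 (0.0825) or 3 (0.0609), with log2 fold changes from -0.59 to -0.50. The call also ended with no filter and with the replicate block. Astrocytes held at most 0.1 TPM in controls and at most 0.3 TPM in KO animals, below the filter of the fit (exact two-sided permutation p = 0.230 over 126 assignments). A TPM over the whole gene need not fall in proportion when part of a gene is deleted.

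**Figure D1:**
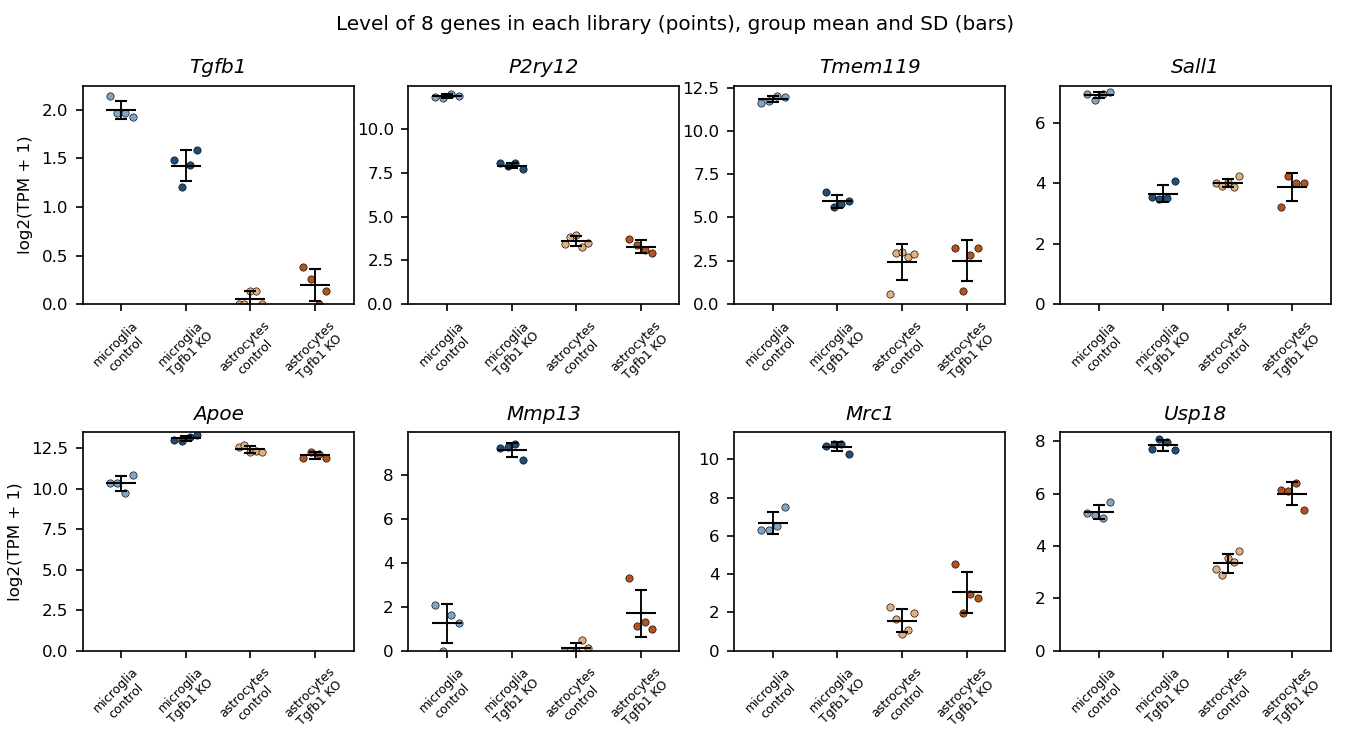
Level of 8 genes in each library as log2(TPM + 1), with a point per library and the mean and SD of each of the 4 groups. In microglia Tgfb1, P2ry12, Tmem119 and Sall1 were lower and Apoe, Mmp13, Mrc1 and Usp18 higher in KO animals, while Usp18 alone passed the threshold in astrocytes.

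The comparison of KO with control microglia asked what loss of Tgfb1 in Cx3cr1-expressing cells does to microglia. Genes that mark resting microglia fell together in the KO animals. P2ry12 fell from 3747 ± 273 to 241 ± 27.9 TPM (SD, n = 4 in each group; log2 fold change -3.95, SE 0.10, limma adjusted p = 1.9e-08), and Tmem119, a microglial surface marker, fell from 3659 ± 472 to 62.4 ± 17.8 TPM (SD, n = 4; log2 fold change -5.88). Sall1, a transcription factor of microglial identity, fell from 121 ± 8.75 to 11.8 ± 2.67 TPM (SD, n = 4), and Cx3cr1, the fractalkine receptor, from 1612 ± 128 to 477 ± 69.1 TPM (SD, n = 4). Of 33 tested homeostatic genes 31 fell, 1 rose (Gas6) and 1 did not pass (Mef2c), the same counts as adjusted over the list alone. This was the only list of the 31 tested in microglia whose call held with an estimated correlation (limma camera, adjusted p = 5.5e-26; adjusted p = 0.0304 with an estimated correlation). Among its members Slc2a5, a fructose transporter, fell by 5.11 and Golm1, a Golgi membrane protein gene, by 4.71 on the log2 scale. Gas6 and Mef2c were picked for mention after their values were seen.

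The largest changes of single genes in KO microglia went both ways. Mmp13, a collagenase, rose from 1.68 ± 1.34 to 571 ± 111 TPM (SD, n = 4; log2 fold change 7.90), and Spic, a transcription factor of iron-recycling macrophages, had a log2 fold change of 6.06. The next largest rises were those of Cd300ld (5.83), the chemokine gene Ccl7 (5.42), the inhibitory receptor genes Lilr4b (5.37) and Lilrb4a (5.11), Aoah, which inactivates lipopolysaccharide (4.98), and Ifi205 (4.93). Upk1b (-6.75), Ecscr (-6.74) and Sparc, a secreted matrix protein gene (-6.08), showed the largest falls. Thrsp (-5.75), the sialomucin gene Cd34 (-5.47), the protease inhibitor gene Serpine2 (-5.35) and Il7r (-5.12) followed. Lilr4b and Lilrb4a, and Ifi205 with its paralogs, share sequence, and how reads that map to more than 1 place were treated is not stated.

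Genes of the TGF-beta pathway moved both ways. Tgfbr1, a signalling receptor, fell from 448 ± 100.4 to 77.3 ± 19.1 TPM (SD, n = 4), whereas Tgfbr2, its partner, was at 77.8 ± 5.72 TPM in controls and 100.5 ± 22 TPM in KO animals (SD, n = 4) and did not pass (limma adjusted p = 0.129). Smad7, an inhibitor that TGF-beta signalling induces, fell from 12.1 ± 2.54 to 2.27 ± 1.31 TPM (SD, n = 4). Of 15 tested ligands, receptors and activators 2 rose, 5 fell and 8 did not pass, against 3 and 6 adjusted over the list alone (camera adjusted p = 0.320). They included the co-receptor gene Eng (-2.11), the integrin gene Itgav (-1.81) and the ligand gene Tgfb3, which rose from 0.0250 ± 0.05 to 2.27 ± 0.737 TPM (SD, n = 4). Of 16 response genes 2 rose, 7 fell and 7 did not pass, as they did adjusted over the list alone. That list was lower (limma camera, adjusted p = 0.0314; adjusted p = 0.306 with an estimated correlation), and its call ended against controls without Y-linked RNA (adjusted p = 0.0832). The feedback inhibitors Pmepa1 (-2.67), Ldlrad4 (-2.03), Skil (-1.71) and Ski (-1.45) fell.

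Interferon-stimulated genes rose almost without exception. Of 37 tested members 35 rose and 2 did not pass, 36 rose adjusted over the list alone, and the median log2 fold change was 2.66 (limma camera, adjusted p = 2.9e-24; adjusted p = 0.124 with an estimated correlation). Ifitm3, which restricts viral entry, rose from 110.4 ± 16.7 to 1924 ± 142 TPM (SD, n = 4), and Oas1a and Oasl2, of the oligoadenylate synthetase family, rose by 3.22 and 3.81 on the log2 scale. Class I antigen presentation genes rose for 12 of 19 with none lower, 13 adjusted over the list alone (adjusted p = 1.0e-06; adjusted p = 0.293 with an estimated correlation), among them H2-K1 (1.92) and H2-D1 (1.67). Class II genes split: 4 rose and 4 fell, as they did adjusted over the list alone, and the median was positive while the mean and the test were negative (adjusted p = 0.618). Cd74, the invariant chain gene, rose from 1226 ± 525 to 3791 ± 681 TPM (SD, n = 4), and H2-Oa, of a peptide-loading modulator, fell from 149 ± 13.9 to 6.60 ± 2.69 TPM (SD, n = 4). Cytokine and chemokine genes rose for 12 of 22 and fell for 5, against 14 and 5 adjusted over the list alone (adjusted p = 0.00472; adjusted p = 0.306 with an estimated correlation). The chemokine gene Ccl12 rose by 4.28 and Cxcl16 by 2.42 on the log2 scale, whereas Ccl9 fell by 3.85. Immediate-early and dissociation stress genes were higher as a list in the same KO libraries (adjusted p = 5.3e-04; adjusted p = 0.398 with an estimated correlation). Mitochondrially encoded genes held 2.95% to 3.57% of TPM in KO and 2.11% to 2.56% in control microglia. Whether cell handling differed between the groups cannot be told from the files.

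Genes of activated and lipid-laden microglia changed in part. Apoe, the main brain apolipoprotein gene, rose from 1335 ± 394 to 8951 ± 948 TPM (SD, n = 4; log2 fold change 2.79). Of 32 disease-associated genes 18 rose, 7 fell and 7 did not pass, against 18 and 9 adjusted over the list alone (limma camera, adjusted p = 0.00320; adjusted p = 0.352 with an estimated correlation). Lilrb4a (5.11) and Cybb, the catalytic subunit gene of the phagocyte oxidase (4.67), rose, while Ctsd, a lysosomal protease gene (-2.36), and the tetraspanin gene Cd9 (-2.12) fell. Lipid handling genes rose for 12 of 23 and fell for 1, against 13 and 2 adjusted over the list alone (adjusted p = 4.1e-04; adjusted p = 0.124 with an estimated correlation). Pltp, a phospholipid transfer protein gene (2.43), Plin2, which coats lipid droplets (2.27), and the cholesterol exporter gene Abcg1 (1.12) were among them. Lysosomal genes rose for 9, fell for 8 and did not pass for 12 of 29, with 13 higher and 8 lower adjusted over the list alone; their median was positive and their mean negative (adjusted p = 0.713). Cholesterol synthesis had 1 of 20 genes past the threshold, Msmo1, which fell by 0.79, and the same adjusted over the list alone (adjusted p = 0.320). Complement genes rose for 7 of 17 and fell for 3, against 7 and 4 adjusted over the list alone (adjusted p = 0.0698; 0.0281 with quantile normalization), with Cfp, the properdin gene, up by 4.60 and Itgam, the complement receptor subunit gene, down to a log2 fold change of -2.87.

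**Figure D2:**
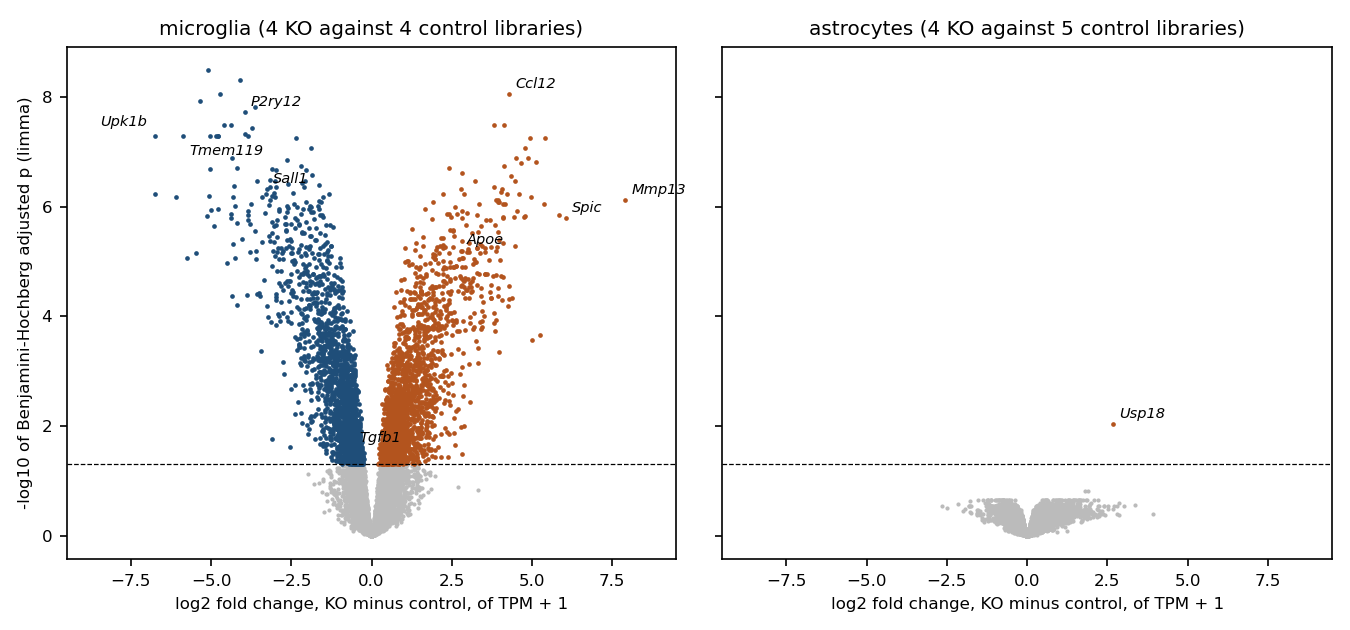
Log2 fold change, KO minus control, of each tested gene against -log10 of its limma adjusted p, for microglia and astrocytes. Points past the dashed line at 0.05 are orange where higher and blue where lower, and grey points did not pass: 3711 genes passed in microglia and 1 in astrocytes.

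Markers of border-associated macrophages, the resident macrophages of meninges and perivascular spaces, moved with these groups. Of 16 tested members 11 rose, 2 fell and 3 did not pass, against 11 and 3 adjusted over the list alone (limma camera, adjusted p = 5.1e-06; adjusted p = 0.306 with an estimated correlation). Pf4 (4.14), Ccl24 (4.22), Clec4n (3.95) and Dab2 (3.97) rose. Of 5 monocyte markers 2 rose and 1 fell, as they did adjusted over the list alone (adjusted p = 0.200), with the integrin gene Itga4 up by 3.91 and Ccr2, the chemokine receptor gene of circulating monocytes, at a log2 fold change of -1.28. Among 3 neutrophil markers Csf3r fell (-1.57), Il1r2 rose (1.38) and 1 did not pass, with 2 higher adjusted over the list alone (adjusted p = 0.772). Lymphocyte markers fell for 2 of 5, Il7r and Klrd1, also adjusted over the list alone (adjusted p = 0.0168; adjusted p = 0.214 with an estimated correlation); the call ended without control animal 2 (adjusted p = 0.411) or 4 (0.524). Neuronal markers rose for 3 of 8, also adjusted over the list alone (adjusted p = 0.00827; adjusted p = 0.306 with an estimated correlation), for example Stmn2 from 0.875 ± 0.465 to 4.65 ± 1.32 TPM (SD, n = 4), and the call ended against controls without Y-linked RNA (adjusted p = 0.0854). Of 15 astrocyte markers 5 rose and 2 fell, against 5 and 3 adjusted over the list alone (adjusted p = 0.200), Aldh1l1 by 1.48 and Slc1a3 with a log2 fold change of -3.42. Oligodendrocyte markers rose for 1 (Trf) and fell for 1 (Mag) of 14, also adjusted over the list alone, with a negative median and a positive mean and test (adjusted p = 0.618); against controls without Y-linked RNA the list was lower (-0.78 relative to all genes, adjusted p = 0.0497), and against those with it higher (0.71, adjusted p = 0.00438). Mag no longer passed without KO animal 1 (adjusted p = 0.0605) or 4 (0.0530). Endothelial markers fell for 2 of 9, Pecam1 and Slc2a1, also adjusted over the list alone, with a positive median and a negative mean and test (adjusted p = 0.320). No mural (6 tested) or ependymal (6 tested) marker passed over all genes or adjusted over the list alone (adjusted p = 0.732 and 0.759), and too few oligodendrocyte precursor markers were expressed to test.

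Over all genes, limma called 3711 of 13054 in microglia, 1857 higher and 1854 lower, of which 1791 changed by at least 1 on the log2 scale. Against the control animals without Y-linked RNA 2955 genes passed, and against those with it 3739. Of the 31 lists 16 passed camera, 13 against controls without Y-linked RNA, 15 against those with it and 1 with an estimated correlation. Of the 3514 calls that could be tested against controls without Y-linked RNA 2481 still passed, in a fit that shares the KO libraries and 2 of the 4 controls. With 4 animals a group, simulated changes of 1 on the log2 scale were recovered for 50% of genes, with noise independent between genes. That simulation changed 200 genes, far fewer than the 3711 called here, and the adjustment is stricter when fewer genes change. The 50% is therefore not a recovery rate for these data.

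Astrocyte libraries carry the animal numbers of the microglia and control animal 3 besides, and were compared to see whether loss of Tgfb1 in Cx3cr1-expressing cells changed them. Usp18, an interferon-induced protease that removes ISG15, rose from 9.42 ± 2.62 TPM in controls (SD, n = 5) to 65.4 ± 18.1 TPM in KO animals (SD, n = 4), with a log2 fold change of 2.66 and an SE of 0.24 (limma adjusted p = 0.00913). It was the 1 gene of 15231 past the threshold in limma, and 1939 had an unadjusted p under 0.05, 1276 higher and 663 lower. The call ended without control animal 1 (adjusted p = 0.0535), KO animal 1 (0.0758) or KO animal 3 (0.0539), each leaving 0 genes, while the log2 fold change stayed between 2.53 and 2.61. In limma 5 genes passed without KO animal 2 and 2 without control animal 5. Genes of astrocyte reactivity did not pass: Gfap, an intermediate filament gene, was at 195 ± 9.49 TPM in controls (SD, n = 5) and 154 ± 45.2 TPM in KO animals (SD, n = 4; limma adjusted p = 0.392). Vim was at 74.2 ± 20 and 129 ± 124 TPM and Serpina3n at 22.7 ± 8.51 and 20.4 ± 4.64 TPM in the same groups (SD, n = 5 and 4). The water channel gene Aqp4 was at 130.3 ± 7.78 and 115 ± 40.2 TPM, Slc1a2 at 340.2 ± 24.1 and 293 ± 102 TPM, and Tgfb2, another TGF-beta ligand gene, at 25.4 ± 4.27 and 22.4 ± 6.41 TPM (SD, n = 5 and 4). Against controls without Y-linked RNA 0 genes passed in limma (2318 at an unadjusted p under 0.05), against those with it 3, and 65 with Y-linked RNA as a covariate. With the mural marker level as a covariate 0 passed (751 at an unadjusted p under 0.05), with the replicate block 0, and with 1 fit over all groups 85.

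Interferon response genes stood higher as a list in KO astrocytes. All 30 tested members had positive fold changes with a median of 1.24; 1 passed over all genes and 28 were higher adjusted over the list alone (limma camera, adjusted p = 3.7e-22; adjusted p = 0.207 with an estimated correlation). fry, which tests whether the genes move on balance in 1 direction without comparing them with other genes, gave an adjusted p of 0.00933. The mean log2 fold change relative to all genes was 1.15, against 1.35 with controls without Y-linked RNA and 1.03 with the others. Mean log2(TPM + 1) of the list was between 2.03 and 2.57 in control libraries and between 3.15 and 3.84 in KO libraries. Iigp1, an interferon-induced GTPase gene of the A1 reactive list, was at 0.360 ± 0.321 TPM in controls (SD, n = 5) and 3.83 ± 1.28 TPM in KO animals (SD, n = 4) and did not pass (limma adjusted p = 0.154). RNA of other cells moved with these values: the share of microglial RNA estimated from 22 microglial transcripts was between 0.0769% and 0.257% in control libraries, 1.78% in KO animal 1 and between 0.162% and 0.435% in the other KO libraries.

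Cholesterol synthesis genes stood lower. None of 22 tested members passed over all genes and 19 were lower adjusted over the list alone, with a median log2 fold change of -0.54 (limma camera, adjusted p = 4.9e-19; adjusted p = 0.243 with an estimated correlation). Relative to all genes the mean was -0.65, against -0.72 with controls without Y-linked RNA, -0.59 with the others and -0.40 with the mural marker level as a covariate. Tm7sf2, a sterol reductase gene, was at 202 ± 23.1 TPM in controls (SD, n = 5) and 108 ± 29.1 TPM in KO animals (SD, n = 4; limma adjusted p = 0.221). Astrocyte markers were lower as a list with 0 of 22 past the threshold over all genes and 0 adjusted over the list alone (adjusted p = 3.0e-07; adjusted p = 0.340 with an estimated correlation). Clu, the clusterin gene, was at 3493 ± 356 TPM in controls and 2231 ± 617 TPM in KO animals (SD, n = 5 and 4). Oligodendrocyte markers stood higher in the same KO libraries, so lower levels within astrocytes cannot be told from a smaller share of astrocyte RNA. Glycolysis genes were lower as a list, with 2 of 18 lower adjusted over the list alone (adjusted p = 6.6e-06; adjusted p = 0.340 with an estimated correlation), and their mean relative to all genes moved from -0.25 to -0.15 without KO animal 4. Oxidative phosphorylation genes were lower by a median of -0.10 with none of 25 past the threshold adjusted over the list alone (adjusted p = 4.5e-04; adjusted p = 0.340 with an estimated correlation).

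Markers of oligodendrocytes and of the vessel wall differed between the same astrocyte libraries. All 16 oligodendrocyte markers had positive fold changes, with none past the threshold over all genes or adjusted over the list alone (limma camera, adjusted p = 1.0e-06; adjusted p = 0.340 with an estimated correlation), and the mean relative to all genes moved from 0.57 to 0.26 without KO animal 4. All 16 mural and fibroblast-like markers had positive fold changes with none past either threshold (adjusted p = 1.1e-04; adjusted p = 0.352 with an estimated correlation). The matrix proteoglycan gene Dcn was at 17.1 ± 11.2 TPM in controls (SD, n = 5) and 61.2 ± 42.4 TPM in KO animals (SD, n = 4), and the smooth muscle gene Tagln at 4.22 ± 1.92 and 10.9 ± 5.11 TPM. Of 16 endothelial markers 15 had positive fold changes and none passed either threshold (adjusted p = 0.00186; adjusted p = 0.406 with an estimated correlation); the call ended without KO animal 1 (adjusted p = 0.206).

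**Figure D3:**
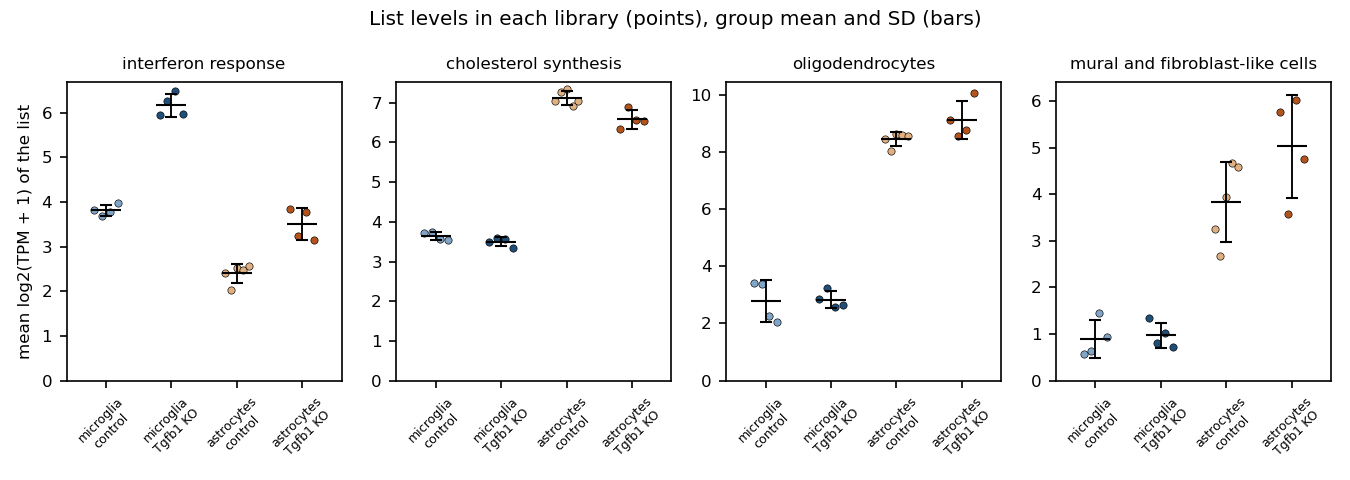
Mean log2(TPM + 1) of the interferon response, cholesterol synthesis, oligodendrocyte and mural lists in each library, with a point per library and the mean and SD of each of the 4 groups. The interferon list lay between 2.03 and 2.57 in control astrocytes and between 3.15 and 3.84 in KO astrocytes.

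By camera in limma 18 lists passed in astrocytes, 11 against controls without Y-linked RNA, 14 against those with it and 0 with an estimated correlation. MHC class I genes were higher (adjusted p = 0.00577; adjusted p = 0.352 with an estimated correlation), 3 of 16 adjusted over the list alone, for example H2-D1 at 177 ± 12.7 TPM in controls and 422 ± 130.2 TPM in KO animals (SD, n = 5 and 4). MHC class II genes were higher for 0 of 7 adjusted over the list alone (adjusted p = 0.00689; adjusted p = 0.352 with an estimated correlation). Both calls ended without KO animal 1 (adjusted p = 0.0800 and 0.104), and H2-D1 passed without KO animal 2 (adjusted p = 0.0121). Genes of the A1 reactive list were higher for 4 and lower for 1 of 12 adjusted over the list alone (adjusted p = 0.00455; adjusted p = 0.340 with an estimated correlation), a call that ended without KO animal 1 (adjusted p = 0.121) or 3 (0.0749). Border-associated macrophage markers were higher for 3 of 6 adjusted over the list alone (adjusted p = 0.00577; adjusted p = 0.340 with an estimated correlation), for example Ms4a7 at 0.1 ± 0.122 and 5.92 ± 6.96 TPM (SD, n = 5 and 4), and the call ended without KO animal 1 (0.105), 2 (0.0558) or 3 (0.0660). RNA of microglia moved with this rise: the estimated share times the level in microglia gave 5.91 TPM for Ms4a7, whose mean rose by 5.82 TPM, and a median of 101.5% of the rise over the 5 members that rose, with Colec12 near 0 TPM of its 49.2. Cytokine and chemokine genes were higher for 2 of 14 adjusted over the list alone (adjusted p = 0.0192; adjusted p = 0.340 with an estimated correlation), until control animal 1 (0.0578), KO animal 1 (0.191) or KO animal 3 (0.0749) was left out. The microglial share gave a median of 52.5% of the rise over the 12 of them that rose, against 25.6% for MHC class II and 18.9% for MHC class I. These shares and Colec12 were chosen for mention after the values were seen. Complement genes were higher for 0 of 14 adjusted over the list alone (adjusted p = 0.0174; adjusted p = 0.362 with an estimated correlation), until control animal 1 (0.0546) or 3 (0.0993) or KO animal 1 (0.242) or 3 (0.152) was left out. Cell cycle genes were higher for 1 of 17 adjusted over the list alone (adjusted p = 0.00717; adjusted p = 0.340 with an estimated correlation). Neuronal markers were higher for 0 of 9 adjusted over the list alone (adjusted p = 0.0453; adjusted p = 0.340 with an estimated correlation), until control animal 3 (0.101), 4 (0.0815) or 5 (0.0996) or KO animal 1 (0.245) was left out. Genes of synapse-related secreted factors and phagocytic receptors were lower for 2 of 17 adjusted over the list alone (adjusted p = 0.0192; adjusted p = 0.340 with an estimated correlation), until KO animal 3 was left out (0.0660) or the values were quantile normalized (0.0755). Lysosomal genes were lower for 2 of 30 adjusted over the list alone, with a negative median and a positive mean (adjusted p = 0.0271; adjusted p = 0.284 with an estimated correlation), until control animal 4 (0.0563) or KO animal 2 (0.0558) or 3 (0.111) was left out. Their mean relative to all genes moved from -0.0628 to -0.114 without KO animal 1, to -0.0397 and -0.0306 without KO animals 2 and 3 in turn, and to 0.00344 with quantile normalization, which ended the call (0.148).

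The remaining 12 lists did not pass in astrocytes. Adjusted over the list alone, 1 of 18 TGF-beta ligands, receptors and activators was higher (limma camera, adjusted p = 0.377), as were 2 of 24 disease-associated microglial genes with 1 lower (adjusted p = 0.805) and 2 of 20 lipid handling genes with 6 lower (adjusted p = 0.129). TGF-beta response genes had 0 of 18 past either threshold, with a positive median and a negative test (adjusted p = 0.915), among them Tgfbi at 8.22 ± 4.71 TPM in controls and 22.1 ± 9.43 TPM in KO animals (SD, n = 5 and 4). Homeostatic microglial genes had 0 of 27, with a negative median and a positive mean (adjusted p = 0.259), and were lower as a list without KO animal 1 (-0.21 relative to all genes, adjusted p = 0.0331). Ribosomal protein genes had 0 of 31 (adjusted p = 0.623) and were lower without KO animal 1 (-0.16 relative to all genes, adjusted p = 0.0331) and higher without KO animal 2 (0.0619, adjusted p = 0.000471). Immediate-early genes had 0 of 25 (adjusted p = 0.148) and passed without KO animal 2 (adjusted p = 0.0281) or with quantile normalization (0.0301). Pan-reactive astrocyte genes had 0 of 10 (adjusted p = 0.0868) and passed without control animal 2 (0.0427) or KO animal 2 (0.0281) and with quantile normalization (0.0268). Genes of the A2 reactive list had 0 of 7 (adjusted p = 0.122) and passed without KO animal 4 (0.0316). Monocyte markers had 0 of 6 (adjusted p = 0.404) and oligodendrocyte precursor markers 0 of 7 (adjusted p = 0.181). Of 12 ependymal and choroid plexus markers 1 was higher adjusted over the list alone (adjusted p = 0.169), and the list passed without control animal 1 (0.0494) or 2 (0.0266).

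**Figure D4:**
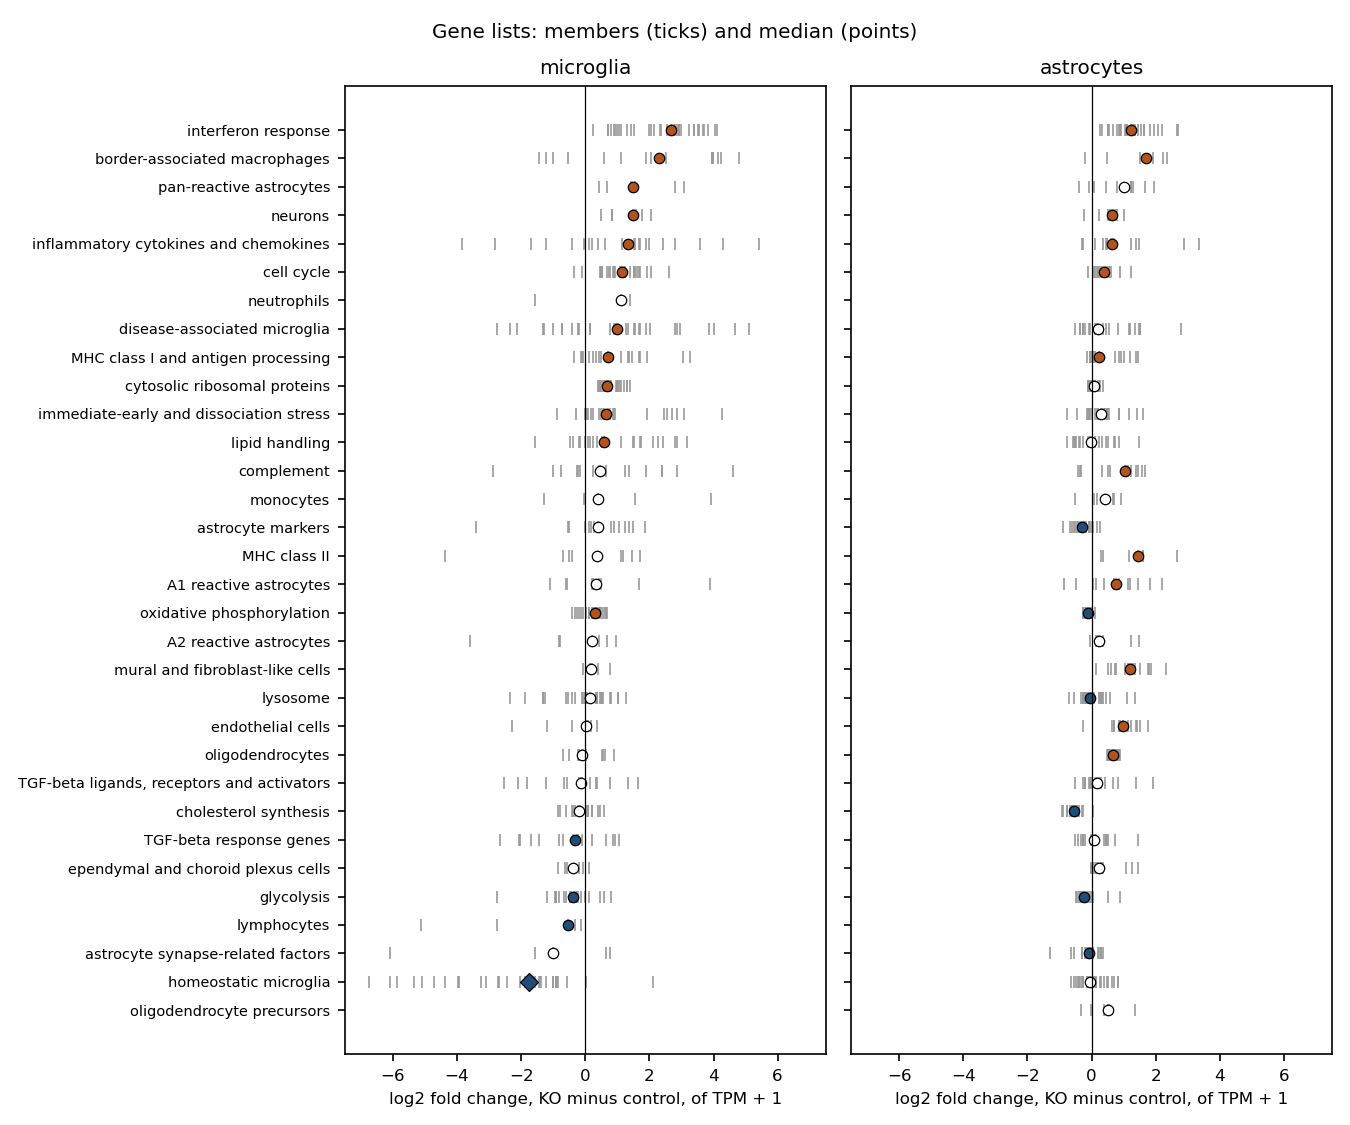
Log2 fold change, KO minus control, of each tested member (ticks) and the median (points) of each gene list in microglia and astrocytes. Filled orange and blue points passed camera as higher and lower, open points did not, and the diamond marks the homeostatic list in microglia, which also passed with an estimated correlation.

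The KO effect was also tested for a difference between the cell types, since a gene past the threshold in microglia and not in astrocytes is not shown to differ. Mmp13 had the largest difference towards microglia, 6.33 on the log2 scale with an SE of 0.63 (limma adjusted p = 2.2e-06), followed by Spic (5.59), Cfp (4.97), the DNase gene Dnase1l3 (4.63) and Aoah (4.55). The largest in the other direction were those of Ecscr (-6.92), Cd34 (-6.87), Upk1b (-6.28), Sparc (-6.04) and Tmem119 (-5.96). Of the difference of Cd34, 1.39 lay in the astrocyte libraries, where it did not pass (adjusted p = 0.407) and where endothelial markers also stood higher. limma called 2648 of 17087 genes, 1133 with a higher and 1515 with a lower effect in microglia, and 2990 with Y-linked RNA as a covariate. A gene could enter this fit through its microglia libraries alone. For a gene that astrocytes hardly express, the difference restates the change in microglia and tells nothing of a response of astrocytes.

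Usp18 was the 1 gene called higher in both cell types. Of 11524 genes tested in both, 1464 were higher in microglia and 1 in astrocytes, and 0.127 shared genes would be expected (one-sided Fisher's exact test, p = 0.127). This is the smallest p that 1 call in astrocytes allows, so the test could not pass and does not tell whether responses are shared. In the lower direction 1496 genes passed in microglia and 0 in astrocytes in limma, so no overlap could be tested. The overlap was 0 without control astrocyte animal 1, KO astrocyte animal 1 or 3, and 2 without KO astrocyte animal 2. Of the 2960 microglial calls tested in both cell types, 53.0% had the same sign in astrocytes, against 50.3% of all 11524 genes. Across genes, which are not independent replicates, the fold changes of the cell types had a Pearson r of 0.144 and a Spearman rho of 0.0470.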

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

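Splits of the samples and the test of microglial RNA were set before the results were seen, and the tests of border-associated macrophages, composition, vascular RNA and sex were chosen only after the result was seen. For KO against control microglia, 1 of the 35 splits of the 8 libraries, the real one, gave as many as 3711 genes. The highest other split gave 1. This is the smallest share that 35 splits allow, so chance is unlikely for this number. For gene lists in microglia 1 of 35 splits gave as many as 16, with 14 as the highest other and a median of 7 in the others. Chance is unlikely only for the number at camera's preset correlation, and there a split that mixed genotypes came close with 14. The number fell from 16 to 1 with an estimated correlation. Splits other than the real one passed several lists too, so the call of a single list at the preset correlation is weak evidence. In astrocytes 12 of 100 splits gave at least the 1 gene of the real one, so chance cannot be excluded. The highest other split gave 168 genes; it set control animals 1, 2 and 3 and KO animal 2 against control animals 4 and 5 and KO animals 1, 3 and 4, which points to a structure of the samples apart from genotype. The mean log2(TPM + 1) of the mural list was between 2.68 and 3.94 in the former and between 4.59 and 6.02 in the latter. For gene lists in astrocytes 4 of 100 splits, the real one among them, gave as many as the real 18, with 21 as the highest other and a median of 7 in the others. Since other splits gave as many or more, and the samples held a structure apart from genotype, chance is not excluded. The number fell from 18 to 7 without KO animals 1 and 3 and to 0 with an estimated correlation. For control microglia against control astrocytes 1 of 100 splits gave as many as 10078 genes (highest other 6533), and chance is unlikely. For the difference of the KO effect 1 of 70 assignments of genotypes to the 8 animals with both cell types gave as many as 2648 genes. The highest other, 2572, exchanged the genotypes of all 8 animals, and the next gave 1, so chance is unlikely.

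Border-associated macrophage genes were higher in KO microglia for 11 of 16 tested members, with Mrc1 at 108 ± 50.9 TPM in controls and 1629 ± 252 TPM in KO animals (SD, n = 4). A larger share of unchanged border-associated macrophages in the sort, whose gate the labels do not give, would bring all of their transcripts. Of the 16 members 2 fell, Cd209f from 10.9 ± 3.34 to 3.38 ± 1.08 TPM and Cbr2 from 60.2 ± 14.6 to 40.4 ± 2.55 TPM. These falls do not decide the question. Of all 13054 tested genes 1854 fell, a share like that of these 2 members, so some fall among 16 was likely in any case. A larger share of these cells stays open as a source of the 11 rises. Control microglia 5 also stood apart on this list (4.77 against 3.97 to 4.10 in the other controls). A shift of TPM composition would move all genes by about the same amount. The median log2 fold change was 0.00399 over all 13054 tested genes (SD across genes 0.879) and 2.29 over the 16 members. This test could hardly have come out otherwise. The 10 highest genes held at most 14.51% of TPM in control and 10.79% in KO microglia, too little for a shift of that size. Border-associated macrophages that themselves changed with Tgfb1 loss, and a shift of microglia towards these genes, stay open and cannot be separated in sorted bulk RNA. A change of microglial state may be one source, as a hypothesis only, and Mrc1, Cd209f and Cbr2 were picked for mention after their values were seen.

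Sex-linked RNA differed between the groups, since no KO animal had Y-linked RNA and 2 of the 4 control microglia libraries did. A difference in sex between the groups as the whole cause of the microglial calls is argued against: 2955 of all tested genes passed against the controls without Y-linked RNA, which are of the same kind as every KO animal. Sex may still add to single genes, and its interaction with genotype was not testable because every KO animal was of 1 kind.

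Interferon response genes were higher in KO astrocytes, where 30 of 30 tested members had positive fold changes. Microglial RNA in the astrocyte libraries could carry such genes over, but the estimated share of 0.155% in controls and 0.595% in KO libraries gave a median of 5.12% of the members' rise in TPM, from 0.993% to 69.4%, and more than 50% for 1 of 30. A larger amount of otherwise unchanged vascular RNA in the astrocyte libraries is argued against as the whole cause. The list's mean relative to all genes was 0.90 with the mural marker level as a covariate (camera adjusted p = 2.8e-23) against 1.15 without it. The covariate cannot remove a rise of these genes within vascular cells, and oligodendrocyte RNA was not tested as a source. A difference in sex between the groups is likewise argued against, with a mean of 1.35 against the controls without Y-linked RNA (adjusted p = 4.1e-14). An interferon response of astrocytes or of other cells in their libraries may remain, as a hypothesis, and the call of the list was lost with an estimated correlation (adjusted p = 0.207).

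Single libraries lay far from the others of their group in 7 of 140 groups of values (5%), and chance alone puts about 1 in 20 groups beyond this limit. The mean log2(TPM + 1) of border-associated macrophage markers was 4.77 in control microglia 5 against 3.97 to 4.10 in the others, and that of neutrophil markers 1.18 in control microglia 2 against 0.45 to 0.56. Cytokine and chemokine genes were at 4.80 in KO microglia 4 against 4.98 to 5.01, and complement genes at 5.67 in KO microglia 3 against 5.45 to 5.47. Oligodendrocyte precursor markers were at 0.25 in KO microglia 4 against 0.40 to 0.42. In KO astrocytes 2, 15057 genes were listed at 0 against 13647 to 13782 in the other KO astrocytes, and lymphocyte markers were at 0.0916 against 0.27 to 0.29.

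The KO effect differed between microglia and astrocytes, by the test of the difference in limma, for Mmp13 (6.33 on the log2 scale, microglia minus astrocytes), Spic (5.59), Cfp (4.97), Dnase1l3 (4.63), Aoah (4.55), Ecscr (-6.92), Cd34 (-6.87), Upk1b (-6.28), Sparc (-6.04) and Tmem119 (-5.96). Genes could enter this test through microglia libraries alone, so such a difference can restate the change in microglia. In the library that belongs to no group, the mean log2(TPM + 1) of homeostatic microglial genes was 8.59, against 3.23 to 3.54 in control astrocytes.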

How the results depend on the processing

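The fits with Y-linked RNA, with each kind of control, with the mural marker level, without KO astrocytes 1 and 3, and with quantile normalization for gene lists were chosen after seeing the data, and for the changes below the cause was not tested unless given. KO against control microglia gave between 2735 and 4438 genes under the other alternatives and 2079 with the replicate block. Genotypes share only numbers. Deviations from the group mean of libraries with equal numbers correlated across genes at 0.00260 to 0.0232 in microglia and at -0.0918 to 0.185 in astrocytes. In astrocytes 1 gene became 3 with no filter, 0 with the replicate block, 85 with one fit over all groups, which takes its spread from microglia too, 0 to 5 without single libraries, 65 with Y-linked RNA as a covariate, 0 and 3 against controls without and with Y-linked RNA, 0 with the mural covariate and 0 without KO animals 1 and 3. The difference of the KO effect gave 2089 to 3573 genes and control microglia against control astrocytes 7261 to 11150 under all alternatives. In the comparisons that hold both cell types of an animal, the replicate block gave 2401 genes for the difference of the KO effect. It gave 9353 between control cell types and changed no call of the 10 genes named for the difference. Deviations from the group mean in the 2 libraries of a control animal correlated across genes at 0.0895 to 0.219. Each such astrocyte library matched the microglia library of its own animal best, a pairing that the main fit did not use. Between genotypes, which share only numbers, the block ended the calls of TGF-beta response genes (adjusted p = 0.0650) and oxidative phosphorylation (0.0524) in microglia and of lysosomal (0.0804) and synapse-related (0.0610) genes in astrocytes, and pan-reactive genes passed in astrocytes (0.0432). It ended the calls of 9 of 115 named genes in microglia and of 1 of 62 in astrocytes, and changed no other call of a list or named gene apart from Tgfb1 below. Of 31 lists in microglia 16 passed, 1 with an estimated correlation and 23 with fry. Of 30 in astrocytes 18 passed, 0 with an estimated correlation, 1 with fry, 11 against controls without Y-linked RNA and 7 without KO animals 1 and 3. The overlap was 0 to 2 without single libraries. For Tgfb1 in microglia the log2 fold change was -0.796 with a pseudocount of 0.1 TPM (adjusted p = 0.0329) and -0.256 with 5 TPM (0.0210), and the filter at 5 TPM left it out. It was -0.68 with quantile normalization (0.0132), -0.57 with no filter (adjusted p = 0.0900, more genes tested), -0.60 with the replicate block (0.177), -0.62 to -0.50 without single libraries (up to 0.0825), -0.62 against controls without Y-linked RNA (0.0718) and -0.52 against those with it (0.0731). Of 519 list values in microglia 476 kept their side of the threshold, 29 became weaker, 10 stronger and 4 reversed, and of 600 in astrocytes 487, 92, 13 and 8. The reversed means relative to all genes, of lists called in the main or the alternative fit, were these. In microglia oxidative phosphorylation went to -0.0225 with Y-linked RNA as a covariate and -0.0513 against controls without it (0.626), and oligodendrocyte markers were at -0.78 against controls without (0.0497) and 0.71 against controls with Y-linked RNA (0.00438). In astrocytes lysosomal genes were at 0.00344 with quantile normalization (0.148). Ribosomal protein genes were at -0.16 without KO animal 1 (0.0331), 0.0619 without KO animal 2 (0.000471) and -0.16 without KO animals 1 and 3 (0.0123). These 2 animals were picked for their mural RNA, so what mural and endothelial markers lose without them follows from the choice; without them complement was at -0.0046 (0.894) and endothelial markers at -0.0084 (0.714). With the mural covariate endothelial markers were at -0.10 (0.371) and mural markers at -0.0388 (0.581), which the covariate removes by construction. Of 2336 values for 115 named genes in microglia 2285 kept their side of the threshold, 49 became weaker, 2 stronger and 0 reversed. Of 1438 values for 62 genes in astrocytes 1416 kept it, and all 270 for the difference did. The files hold no depth, so its limits are unknown.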

Other observations

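Ribosomal protein and cell cycle genes mostly rose in KO microglia, and stress genes rose in part. Cytosolic ribosomal protein genes rose for 29 of 31 with none lower, all 31 adjusted over the list alone (limma camera, adjusted p = 7.7e-11; adjusted p = 0.349 with an estimated correlation), for example Rps18 (1.20) and Rpl7 (0.64). Cell cycle genes rose for 21 of 29 with none lower, 23 adjusted over the list alone (adjusted p = 8.7e-08; adjusted p = 0.262 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose from 1.6 ± 0.560 to 6.40 ± 1.39 TPM (SD, n = 4), and Stmn1, a tubulin-binding protein gene, by 1.13 on the log2 scale. Immediate-early and dissociation stress genes rose for 10 of 24 and fell for 1, against 11 and 2 adjusted over the list alone (adjusted p = 5.3e-04; adjusted p = 0.398 with an estimated correlation). Fos rose from 7.25 ± 5.26 to 139.6 ± 36.2 TPM (SD, n = 4) and Dusp1, a phosphatase gene, by 3.09 on the log2 scale. Glycolysis genes fell for 10 of 20 and rose for 1, against 11 and 2 adjusted over the list alone (adjusted p = 0.00333; adjusted p = 0.306 with an estimated correlation), with the lactate exporter gene Slc16a3 at -2.75, the hexokinase gene Hk2 at -0.93 and Gpi1 at 0.80; against controls with Y-linked RNA alone the list did not pass (adjusted p = 0.0541). Oxidative phosphorylation genes rose for 7 of 25 and fell for 2, against 10 and 2 adjusted over the list alone (adjusted p = 0.0368; adjusted p = 0.579 with an estimated correlation), among them Cox5a (0.65) and Cox5b (0.65). That call ended without control animal 4 (adjusted p = 0.157) or 5 (0.129), without KO animal 1 (0.0522), against controls without Y-linked RNA (0.626) and with quantile normalization (0.128), which left 2 members higher and 2 lower.

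Lists written for astrocytes also held genes that microglia express. Pan-reactive genes rose for 3 of 6 with none lower, 4 adjusted over the list alone (limma camera, adjusted p = 0.00668; adjusted p = 0.166 with an estimated correlation), with the ceruloplasmin gene Cp from 3.12 ± 1.70 to 32.7 ± 6.85 TPM (SD, n = 4). Genes of the A1 list rose for 3 and fell for 1 of 10, against 3 and 2 adjusted over the list alone (adjusted p = 0.159), among them Iigp1 (3.88). Genes of the A2 list fell for 3 of 7, with 1 higher and 3 lower adjusted over the list alone and a positive median with a negative mean and test (adjusted p = 0.322), for example the cytokine gene Clcf1 (-3.58). Synapse-related secreted factors and phagocytic receptors fell for 3 of 5, with 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.101), among them Thbs2 (-1.56) and the phagocytic receptor gene Mertk (-1.01); the list passed without KO animal 1 (adjusted p = 0.0324).

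The library in no group had a Pearson r across genes between 0.967 and 0.981 with control microglia, between 0.937 and 0.943 with KO microglia, between 0.613 and 0.638 with control astrocytes and between 0.625 and 0.669 with KO astrocytes. It held 46.0 TPM of Ddx3y, 0 TPM of Xist and 2.8 TPM of Tgfb1. Genes are not independent replicates, and it was not moved into a group.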
